A study of Mus musculus with 6 samples.

How the data were processed

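RNA was sequenced from 6 mouse samples, 3 preparations of the KP cell line and 3 lung samples. Per the labels, each lung sample pooled the lungs of 3 mice from a separate experiment, and the mice had received 100000 KP cells in the tail vein 28 days before harvest. The labels' protocols describe collagenase digestion of the lungs, extraction of total RNA with column clean-up and a stranded mRNA library kit, and they also mention a Nugen protocol before hybridization. The same protocol text stands on the cell line samples, so their handling is not described separately. The cell line samples are given as triplicates with no statement that they came from separate cultures, so p-values measure the spread between these preparations, which may be technical in that group.

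The deposited table holds estimated counts per transcript, 1 column per sample, as the authors submitted them, and the totals differ between samples. Per the submitters' processing notes, FastQC 0.11.9, Salmon 1.4.0, DESeq2 1.32.0 and the build GRCm39 were used. The role of DESeq2, the annotation release and any filter on transcripts are not given in the sources used here. The identifier column is headed as a gene identifier but holds mouse transcript identifiers. Of 76776 transcripts, 76521 (99.67%) matched a transcript of GENCODE M21 and were summed to 20687 gene symbols, and 19 symbols joined more than 1 gene identifier. That annotation belongs to another build than the one in the notes, so it was used for names and transcript lengths only and no coordinates are given. The other 255 transcripts held between 0.11% and 0.42% of the counts of a sample and stayed out of the gene tests.

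Estimated counts per sample summed to between 17786758 and 22862396. A count of 0 allows up to 3 counts, which came to between 0.132 and 0.169 CPM (counts scaled to library size) depending on the sample. Such floors and the intervals below cover counting error only. Transcript lengths per sample are not part of the table, so a change in isoform use between groups was not corrected for. Near-identical genes share reads that the transcript quantification splits between them, which leaves single members of the Ccl21 genes, the globin genes, the immunoglobulin genes, the classical H2 genes and processed pseudogenes such as Eif4a-ps4 uncertain.

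Gene sums were rounded to whole numbers and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersions, TMM scaling and the package's expression filter by group. P-values were adjusted by the Benjamini-Hochberg method over the 15212 genes tested, and adjusted p below 0.05 was the threshold. Every adjusted p given for a gene comes from that test unless another is named. The model held the group only. Log2 fold changes are lung minus cell line with standard errors (SE), and levels are CPM on TMM-scaled library sizes, as mean ± SD over n = 3 samples per group. Where a group had 0 counts in all of its samples, the fold is a lower bound against 3 counts over the group. Where it had 1 to 3 counts, the ratio has a 95% exact Poisson interval. A ligand or receptor was called detected in a group at 1 CPM or more in all 3 samples.

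The groups, tests, 40 gene lists, named genes and other settings were set before the data were examined. The named genes were every ligand that fell in lung, the 10 ligands that rose most at 1 CPM or more in lung, the 5 ligands with the highest cell line level, and the 4 receptors with the highest lung level among those that rose. For each other list they were the 2 members past the threshold with the highest level, taken in the direction most members took, plus the 1 of the other direction with the largest change, and all members of a list of tumour genes. Over all genes they were the 8 largest changes each way among genes past the threshold with separate groups and 10 CPM or more in the higher group, leaving out predicted gene models. Not every gene and list under that rule is reported, and genes named outside it are said to be so. Lists were tested with camera from limma 3.58.1, first with a preset correlation of 0.01 between genes and then with an estimated one, and with fry.

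The alternatives were DESeq2 size factors, library size alone, no filter on low counts, 10 or more counts in all 6 samples, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, a 2-fold minimum, glmTreat against 2-fold, and each sample left out in turn. The pseudocount alternative applied to normalized values only and was not needed. Leaving out 2 libraries together was added after the data had been seen, as were 10 further marker lists used in the closing section. The test was tried on simulated data for lung against cell line, with 15010 genes, the means and library sizes of these samples and 100 genes changed at each of 2 fold sizes. It recovered 4% of the 2-fold and 64% of the 4-fold changes with 5.6% false calls. The DESeq2 test recovered 29% and 86% with 27.7% false calls, and limma-voom 4% and 57% with 6.2%. The share of genes changed in the simulation was far below the share called in the real data. The adjusted threshold was therefore stricter there, and these recoveries do not carry over to the real comparison.

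Replicates were compared before averaging. Cell line replicates 2 and 3 were the closest pair, with a chi-square of 2.82 per degree of freedom over 13354 genes, above sampling noise, and all 3 were kept as separate samples. The ligand genes Ccl21d, Ccl26 and Ccl27b were not analysed here. Permutation tests of a single value were exact and two-sided, and 3 against 3 samples cannot give a p below 0.1. Descriptive log2 ratios across libraries used a pseudocount of 1 CPM for the length comparison.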

Results

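The series compared chemokine expression between the KP cell line, a mouse lung tumour line, and whole lung tissue carrying tumours grown from it. The labels do not state the genotype of the line. There were 3 lung samples and 3 cell line samples, and no lung free of tumour. Genes said to rise or fall are higher or lower in whole lung than in the cell line. Whole lung holds many cell types, so expression by normal lung cells cannot be told apart from a response to the tumours. Estimated counts summed to 22862396, 21343239 and 17786758 in lung replicates 1, 2 and 3, and to 22686289, 18978969 and 20954042 in cell line replicates 1, 2 and 3.

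Replicates were not equally alike. Across the tested genes, log2 CPM correlated at 0.997 between cell line replicates 2 and 3, but at 0.964 and 0.963 between replicate 1 and each of them. In lung the correlation was 0.986 between replicates 1 and 3, and 0.939 and 0.915 between replicate 2 and each of them. These values are across genes, which are not independent replicates. In lung replicate 2 the median log2 deviation from the other lung samples was 0.69 in the shortest quartile of transcripts and -0.99 in the longest. In cell line replicate 1 no such trend with length was seen (-0.02 and 0.03).

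Surfactant and secretoglobin genes of the lung epithelium were the largest differences between whole lung and the cell line. Sftpa1, which encodes surfactant protein A, stood at 3248 ± 334 CPM in lung and at 0 counts in the cell line, at least 61990-fold higher. Scgb1a1, a club cell secretory protein, stood at 8883 ± 1512 CPM in lung against 1 count in the cell line (ratio 506600, 95% counting interval 90920 to 20010000), and its fitted log2 fold change of 18.54 was 20.48 without cell line replicate 1. Sftpc, Sftpd, Slc34a2, Scgb3a2, Inmt and Sec14l3 completed the 8 largest increases among the genes with separate groups and 10 CPM or more in lung. In the other direction Cck, a neuropeptide gene, had 0 counts in lung and 51.3 ± 40.0 CPM in the cell line, at least 1088-fold lower in lung. Add2, a membrane skeleton protein, fell by 7.08 on the log2 scale, at 1.56 ± 0.343 against 212 ± 87.7 CPM. Bcat1, an enzyme of branched-chain amino acid breakdown, stood at 0.790 ± 0.154 against 94.0 ± 43.6 CPM, and Dynap, Dlx2, Grem1, Aldh1l2 and the pseudogene Eif4a-ps4 made up the rest. Aldh1l2 was uneven in the cell line, at 412 CPM in replicate 1 against 30.6 and 29.5 CPM in the others, and its log2 fold change of -5.91 was -3.53 without that replicate. That of Eif4a-ps4 was -6.73, and -13.72 without lung replicate 1.

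Of 15212 genes tested, 4758 were higher and 2664 lower in lung (7422, or 48.8%), and 4542 and 2017 of these differed by at least 2-fold. The groups did not overlap in 9457 genes, against 10% of genes by chance for 3 against 3 samples. Scaling by library size alone gave 5210 higher and 1728 lower, so that 75.1% of calls were higher against 64.1% with TMM scaling, with a shift of 0.23 in the median log2 fold change. Without cell line replicate 1 and lung replicate 2, the counts were 6657 and 5425. That fit took its spread from the closest pair of samples in each group, so its p-values and counts are not comparable with the others.

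Chemokine ligands were mostly higher in tumour-bearing lung than in the cell line. Of 36 ligands tested, 29 rose, 1 fell and 6 did not pass the test. The counts adjusted over the list alone were 29 and 2. Ligand transcripts summed to 3142 ± 387 CPM in lung and 307 ± 224 CPM in the cell line, a ratio of 10.2 (exact permutation p = 0.1, the smallest that 3 against 3 samples can give). Without cell line replicate 1, whose sum was 566 against 186 and 169 CPM, the ratio was 17.7. Without lung replicate 2, which differed by transcript length, the ratio was 9.70 and 27 ligands rose. Cxcl15, a lung-restricted chemokine, made up the largest part with 1678 ± 237 CPM in lung and 10 counts over the cell line samples (log2 fold change 13.22, SE 0.90, edgeR adjusted p = 3.11e-05), with 15.60 without cell line replicate 1 and 12.62 without cell line replicate 3. Cxcl14 stood at 100.2 ± 11.2 CPM in lung and at 0 counts in the cell line, at least 1929-fold higher. Ccl6 stood at 262 ± 85.8 against 1.03 ± 0.728 CPM, with a log2 fold change of 7.97, and 8.73 without cell line replicate 1. Ccl21b, Cxcl11, Ccl12, Ccl3 and Ccl11 also had 0 counts in the cell line, with lower bounds from 44.3-fold for Ccl11 to 358-fold for Ccl21b. An unmatched transcript held the same rounded counts as Ccl21b in lung replicates 1, 2 and 3 (621, 259 and 363). Near-identical Ccl21 genes share reads, so the level and bound of Ccl21b depend on how reads were assigned. The fitted log2 fold changes of Cxcl11 and Ccl12, 9.55 and 9.52, were 8.90 and 8.82 without lung replicate 2. The list rose as a set with a preset correlation (camera adjusted p = 9.82e-11), with adjusted p = 0.142 with an estimated correlation. With 10 or more counts required in all 6 samples, the number that rose was 15, because that filter removes ligands near 0 in the cell line.

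**Figure D1:**
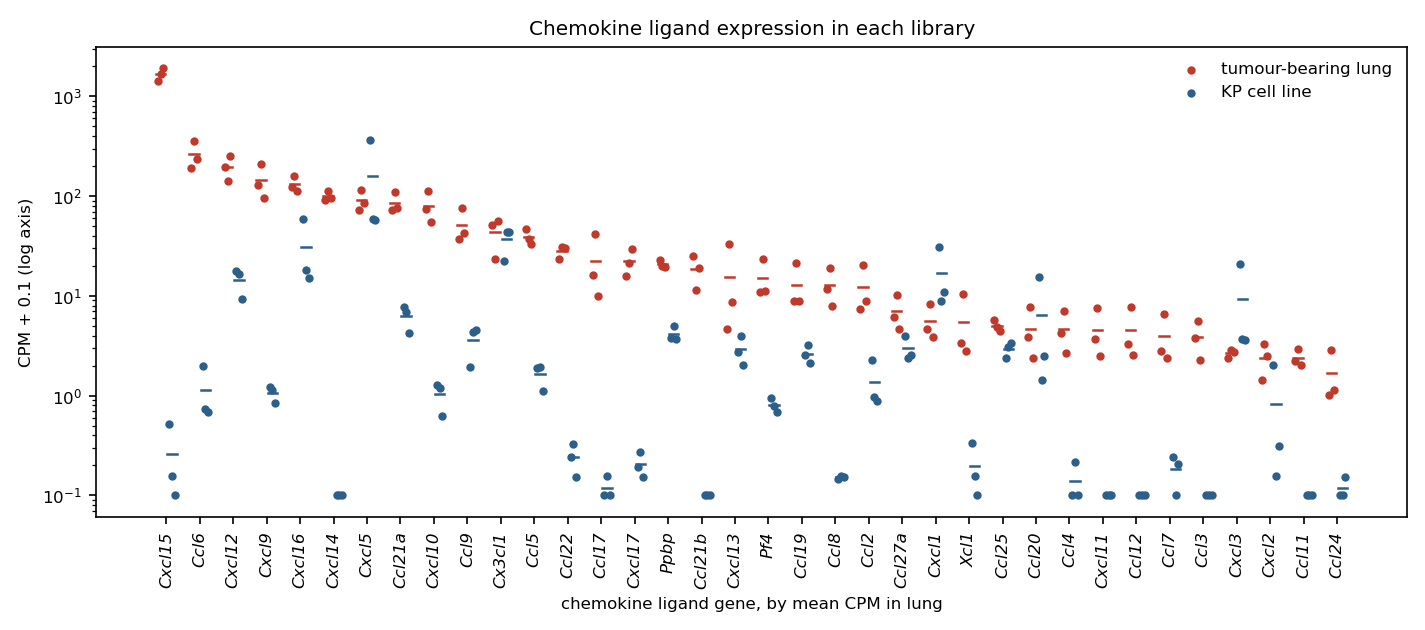
Expression of the 36 tested chemokine ligand genes, ordered along the x axis by mean CPM in lung, with CPM + 0.1 on a log axis. Points are single libraries of lung (red) and cell line (blue), 3 each, with bars at the means: Cxcl15 lies highest in lung at a mean of 1678 CPM, and Cxcl5 has the highest cell line mean at 159.9 CPM, with cell line replicate 1 apart from the other cell line points.

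Grouped by receptor, the ligands of the monocyte receptor Ccr2 all rose (4 of 4). Among them Ccl8 stood at 12.8 ± 5.69 CPM in lung against 3 counts over the cell line samples (ratio 249.9, 95% counting interval 85.5 to 1212), and Ccl2 at 12.1 ± 6.98 against 1.28 ± 0.790 CPM. The log2 fold change of Ccl2 was 3.22, with 2.58 without lung replicate 2 and 3.85 without cell line replicate 1. Ccl9 also rose, at 51.6 ± 20.7 against 3.52 ± 1.48 CPM. All 3 ligands of Cxcr3, the interferon-inducible chemokines that attract T cells, rose. Cxcl9 stood at 145 ± 59.1 against 0.965 ± 0.201 CPM and Cxcl10 at 80.2 ± 29.2 against 0.929 ± 0.350 CPM. Both ligands of Ccr4 rose (2 of 2), with Ccl22 at 28.2 ± 4.09 against 0.141 ± 0.0889 CPM and Ccl17 at 22.5 ± 16.9 CPM against 1 count (ratio 1323, 237.5 to 52260, for counting error alone). Ccl17 stood at 41.7 CPM in lung replicate 2 against 16.1 and 9.77 CPM in the others, and its log2 fold change of 9.91 was 9.05 without that replicate and 11.88 without cell line replicate 2, which held the 1 count. All 3 tested ligands of the lymphoid homing receptor Ccr7 rose, with Ccl21a at 85.7 ± 20.6 against 6.22 ± 1.88 CPM. Median log2 fold changes were 6.59 for the Ccr2 ligands (5.91 with genes at 0 counts set to their bound, and 6.01 without lung replicate 2) and 7.22 for those of Cxcr3 (6.46). The camera adjusted p with the preset correlation was at most 0.0130 for these groups, the value of the Ccr2 ligands. With an estimated correlation it was 0.317 for the Ccr2 ligands, 0.163 for those of Cxcr3, 0.117 for those of Ccr4 and 0.114 for those of Ccr7.

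Ligands of Cxcr2, the main chemokine receptor of neutrophils, went both ways. Of 5, Ppbp rose (20.7 ± 1.82 against 4.06 ± 0.730 CPM), Cxcl1 fell and 3 did not pass the test (camera adjusted p = 0.86). Cxcl1 was the only ligand of the whole list to fall, at 5.48 ± 2.34 CPM in lung and 16.8 ± 12.2 CPM in the cell line (log2 fold change -1.62, SE 0.54, edgeR adjusted p = 0.0379). Its cell line values were 30.9 CPM in replicate 1 and 8.87 and 10.8 CPM in the others. Without cell line replicate 1 its log2 fold change was -0.85 with edgeR adjusted p = 0.116, and Cxcl1 also missed the threshold without lung replicate 1 (edgeR adjusted p = 0.108) or lung replicate 3 (0.0945). The median of the group, -0.82, was 0.63 without cell line replicate 1. Cxcl3 stood at 2.56 ± 0.246 against 9.23 ± 9.83 CPM (edgeR adjusted p = 0.0593), with 20.6 CPM in cell line replicate 1 against 3.63 and 3.48 CPM in the others and a log2 ratio of -0.47 to the mean of those. Cxcl2, Cxcl3 and Cxcl5 were the members below the threshold.

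Fewer ligands were detected in the cell line samples than in lung. At 1 CPM or more in all 3 samples, 15 ligands were detected in the cell line and 35 in lung, and all 15 were among the 35. The cell line samples also held B and T cell transcripts, so detection there does not place a ligand in the KP cells, and this applies to Cxcl12 as well. Cxcl5, a Cxcr2 ligand, was the highest in the cell line at 159.9 ± 176 CPM, followed by Cx3cl1 at 36.7 ± 12.3, Cxcl16 at 30.8 ± 24.8, Cxcl1 at 16.8 ± 12.2 and Cxcl12 at 14.4 ± 4.54 CPM. In lung Cxcl5 stood at 90.7 ± 21.6 CPM, which did not differ past the threshold (log2 fold change -0.82, SE 0.70, edgeR adjusted p = 0.359). Cxcl5 reached 364 CPM in cell line replicate 1 against 58.5 and 57.8 CPM in the others, and without replicate 1 its log2 fold change was 0.63 (edgeR adjusted p = 0.0947). Cx3cl1, the membrane-bound chemokine fractalkine, stood at 43.7 ± 17.7 CPM in lung, a difference of 0.25 on the log2 scale (edgeR adjusted p = 0.635), and of -0.02 without cell line replicate 1. Cxcl16 stood at 59.5 CPM in cell line replicate 1 against 17.9 and 15.1 CPM in the others, and the order of Cxcl16, Cxcl1 and Cxcl12 in the cell line rests on that replicate. Cxcl16 and Cxcl12 were higher in lung, at 131 ± 24.98 and 197 ± 54.95 CPM, and the log2 fold change of Cxcl16 was 2.09, and 2.98 without cell line replicate 1. Ccl20 and Ccl25 were the other ligands below the threshold (edgeR adjusted p = 0.675 and 0.0852), and Ccl20, Ccl25, Cxcl2 and Cxcl3 were named after their values were seen.

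Cell line replicates 2 and 3, the closest pair, were compared for 20 ligands with intervals that cover counting error alone, not the spread between preparations. The SE of a list median was taken over the genes of the list, which are not independent replicates. The ratio of replicate 3 to replicate 2 ran from 0.504 for Cxcl10 (0.1999 to 1.09) to 1.80 for Ccl20 (1.09 to 3.16), with a median log2 ratio of -0.18 (SE 0.13), against -0.78 (SE 0.04) for B and plasma cell markers and -0.84 (SE 0.22) for T cell markers. It was 0.989 for Cxcl5 (95% exact binomial interval 0.907 to 1.08) and 0.991 for Cx3cl1 (0.897 to 1.09). It was 0.557 for Cxcl12 (0.458 to 0.673), 0.602 for Ccl21a (0.445 to 0.804), 0.511 for Cxcl13 (0.329 to 0.766), 0.649 for Ccl19 (0.4135 to 0.993) and 0.555 for Ccl5 (0.291 to 0.988). Cxcl13, Ccl19 and Ccl5 were named after their values were seen.

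**Figure D2:**
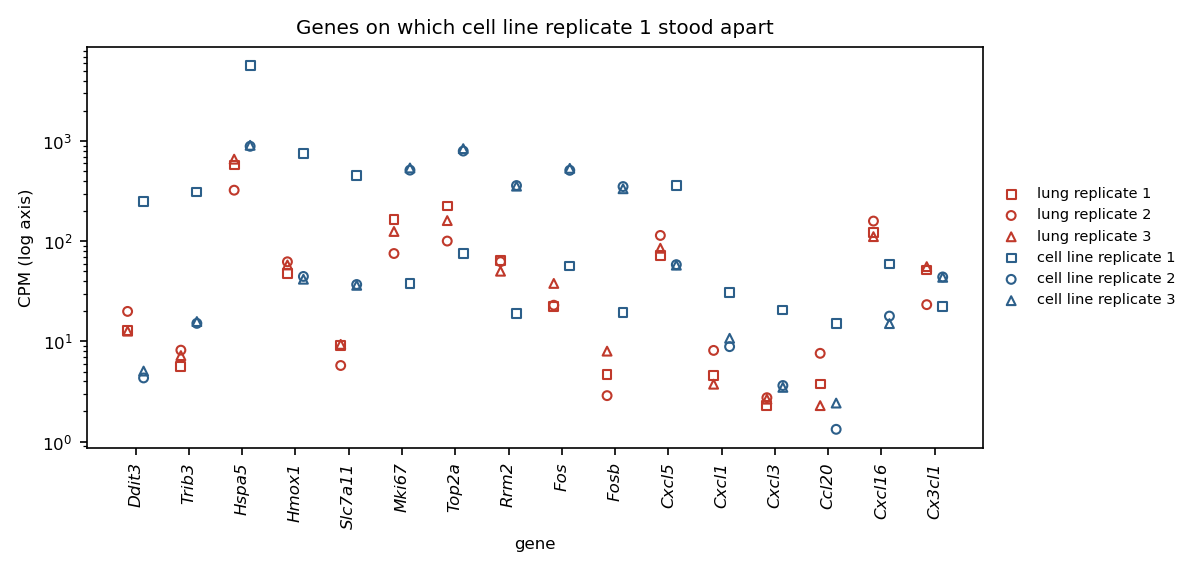
CPM on a log axis of 16 genes in each of the 6 libraries (lung red, cell line blue, 1 symbol per replicate number), chosen after their values were seen. Cell line replicate 1 lies apart from cell line replicates 2 and 3, with Ddit3 at 249.8 against 4.32 and 5.06 CPM, and Mki67 at 37.9 against 514 and 540.3 CPM.

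Chemokine receptors rose in lung in 19 of 21 tested genes, and 20 passed when adjusted over the list alone. Ccr2 stood at 81.8 ± 21.1 against 1.41 ± 0.831 CPM (log2 fold change 5.84, SE 0.51, edgeR adjusted p = 7.01e-05). Cxcr4 stood at 62.4 ± 13.9 against 2.89 ± 0.867 CPM, and Ccr1 at 26.4 ± 2.04 against 2.93 ± 1.75 CPM. No receptor fell by the edgeR test (0 of 21, and 0 at an unadjusted p under 0.05, with 0 by DESeq2 and by limma-voom). Ackr3, a scavenging receptor of Cxcl12, was at 42.4 ± 1.85 CPM in lung and 52.9 ± 3.95 CPM in the cell line, its highest chemokine receptor (log2 fold change -0.32, SE 0.21, edgeR adjusted p = 0.247), and Ccr6 was the other receptor below the threshold. Without cell line replicate 1 and lung replicate 2, 1 receptor fell. Detected receptors numbered 20 in lung and 4 in the cell line samples, where detection does not place a receptor in the KP cells. From cell line replicate 2 to 3, Ccr7 went from 3.11 to 2.53, Cxcr4 from 2.94 to 2.002 and Cxcr5 from 5.13 to 3.48 CPM, while Ackr3 went from 53.3 to 56.7 CPM. Ccr7 and Cxcr5 were named after their values were seen. The camera adjusted p was 8.50e-09 with the preset and 0.0651 with an estimated correlation.

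Markers of lung epithelium and stroma were higher in whole lung in nearly every list. All 10 alveolar type 2 markers rose, with Sftpc at 11310 ± 4109 CPM in lung against 2 counts (ratio 326100, 95% counting interval 90260 to 2692000). Of 9 alveolar type 1 markers 8 rose, with Ager at 911 ± 136 against 0.259 ± 0.225 CPM and Emp2 at 629 ± 161 against 137 ± 126 CPM, whose log2 fold change of 2.20 was 3.27 without cell line replicate 1 and whose call was lost without cell line replicate 2 or 3 (edgeR adjusted p = 0.0552 and 0.0593). All 11 airway epithelial markers rose, with Cyp2f2 at 855 ± 376 CPM against 2 counts (ratio 23930, 6624 to 197600). All 16 endothelial markers rose, with Pecam1 at 367 ± 116 against 3.73 ± 1.22 CPM and Cdh5 at 354 ± 205 against 1.60 ± 0.226 CPM. Of 14 fibroblast markers 13 rose, with Col3a1 at 972 ± 551 against 4.34 ± 1.41 CPM, and all 11 smooth muscle and pericyte markers rose, with Acta2 at 165 ± 64.7 against 8.87 ± 3.36 CPM and Pdgfrb at 135 ± 55.1 against 2.20 ± 1.255 CPM. Median log2 fold changes were 14.15 for alveolar type 2 (13.89 with genes at 0 counts set to their bound), 12.39 for airway (9.14 at the bound) and 7.53 for endothelial markers. Leaving out 1 sample gave 10.86 for airway without lung replicate 3, and 14.85 and 14.89 for alveolar type 2 without cell line replicate 1 and 3. The log2 fold change of Ager was 11.75, and 11.12 without cell line replicate 3. With an estimated correlation the alveolar type 1 and 2, endothelial and smooth muscle lists held (camera adjusted p = 0.037 for each). With the preset correlation all 6 lists had camera adjusted p of 2.01e-08 or less. The airway list had adjusted p = 0.0801 with an estimated correlation, and the fibroblast list 0.0638.

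Of 5 mesothelial markers 4 rose, with Upk3b at 47.4 ± 25.7 against 0.264 ± 0.144 CPM and Upk1b at 33.7 ± 7.76 against 0.388 ± 0.144 CPM, and Msln, which encodes the surface protein mesothelin, fell (176 ± 47.3 against 708 ± 176 CPM). The list had camera adjusted p = 0.0132 with the preset and adjusted p = 0.323 with an estimated correlation. Without cell line replicate 1 the preset adjusted p was 0.071, which missed the threshold. The median log2 fold change of the list, 6.40, was -1.82 where 10 or more counts were required in all 6 samples. All 7 red cell markers rose, with Hbb-bs at 561 ± 394 against 6.44 ± 1.93 CPM and Hba-a2 at 294 ± 175 against 4.69 ± 1.94 CPM (camera adjusted p = 0.00672, and adjusted p = 0.335 with an estimated correlation). Hbb-bs stood at 999 CPM in lung replicate 2 and at 234 and 451 CPM in the other lung samples, and its log2 fold change of 6.44 was 5.68 without that replicate.

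**Figure D3:**
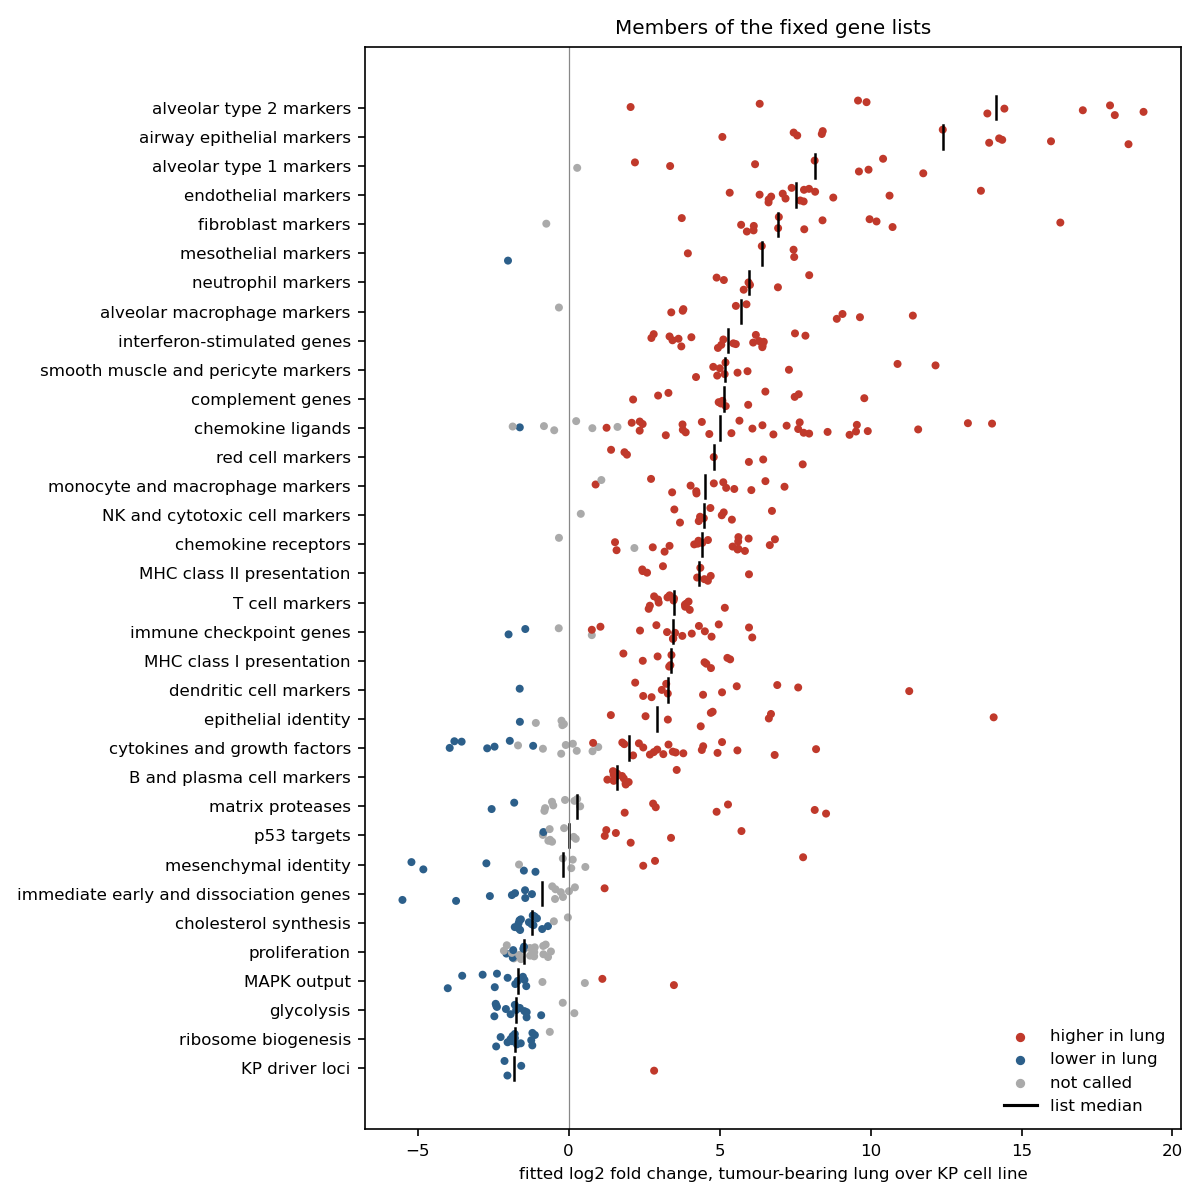
Fitted log2 fold change of lung over cell line on the x axis for every tested member of the fixed gene lists, 1 list per line, leaving out the ligand groups by receptor. Points are genes, coloured by whether they rose, fell or missed the threshold, and black bars are medians, with alveolar type 2 markers highest at 14.15; the bar of mesenchymal identity, at -0.19, is at 0.06 when scaled by library size alone, and fitted values of genes at 0 counts depend on the prior count.

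Immune cell markers were also higher in lung. All 15 T cell markers rose, with Trbc2 at 37.4 ± 10.7 against 3.35 ± 1.31 CPM and Lck at 35.3 ± 0.333 against 4.52 ± 2.36 CPM, and 10 of 11 markers of natural killer and cytotoxic cells, with Nkg7 at 29.5 ± 6.35 against 1.13 ± 0.299 CPM and Gzma at 21.2 ± 7.78 against 0.589 ± 0.385 CPM. Of 14 monocyte and macrophage markers 13 rose, with Lyz2 at 6759 ± 1055 against 47.6 ± 14.01 CPM and C1qa at 221 ± 101 against 3.33 ± 1.14 CPM. Of 10 alveolar macrophage markers 9 rose, with Chil3 at 628 ± 129 against 0.775 ± 0.130 CPM and Ear2 at 96.4 ± 36.0 against 0.174 ± 0.0634 CPM. All 7 tested neutrophil markers rose, with S100a9 at 84.6 ± 51.3 against 0.684 ± 0.288 CPM and Csf3r at 59.3 ± 28.9 against 0.917 ± 0.0193 CPM. The log2 fold change of S100a9 was 6.93, and 6.25 without lung replicate 2, and that of Gzma was 5.14, and 5.73 without cell line replicate 1. Of 13 dendritic cell markers 12 rose, with Itgax at 104 ± 47.2 against 2.19 ± 0.532 CPM and Irf8 at 91.0 ± 9.25 against 9.67 ± 2.51 CPM, and Fscn1, an actin-bundling protein, fell (85.8 ± 16.7 against 264 ± 54.8 CPM). The camera adjusted p was at most 1.02e-05 for these 6 lists with the preset, the value of the neutrophil list. With an estimated correlation it was 0.114 for T cells, 0.171 for cytotoxic cells, 0.0638 for monocytes and macrophages, 0.0581 for both alveolar macrophages and neutrophils, and 0.0801 for dendritic cells.

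B and plasma cell markers had the smallest difference among the immune lists. All 13 rose, with a median log2 fold change of 1.60. The immunoglobulin chain genes Ighm and Igkc stood at 463 ± 210 and 263 ± 130 CPM in lung and at 167 ± 50.8 and 92.4 ± 25.3 CPM in the cell line. The list had camera adjusted p = 0.0165 with the preset and 0.509 with an estimated correlation. Without cell line replicate 3, 7 of the 13 rose, and the edgeR adjusted p was 0.077 for Ighm and 0.0641 for Igkc. In the cell line samples the B and plasma cell markers stood at a median of 32.8% of their lung level, T cell markers at 8.96% and monocyte and macrophage markers at 4.43%, while 10 lung epithelial genes stood at 0.00166%.

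Interferon-stimulated and antigen presentation genes rose together. All 20 interferon-stimulated genes rose, with a median log2 fold change of 5.29, and 5.92 without cell line replicate 1. The guanylate-binding protein gene Gbp2 stood at 371 ± 37.2 against 1.61 ± 0.358 CPM. All 11 genes of MHC class I presentation rose, with B2m at 2052 ± 382 against 198 ± 87.1 CPM and H2-D1 at 1773 ± 93.6 against 176 ± 28.6 CPM. All 10 genes of MHC class II presentation rose, with Cd74 at 2234 ± 314 against 109 ± 34.4 CPM and H2-Aa at 1048 ± 276 against 42.8 ± 13.3 CPM. All 12 complement genes rose, with C3 at 786 ± 506 against 25.1 ± 9.83 CPM and Serping1 at 378 ± 74.0 against 1.91 ± 0.411 CPM. Of 20 immune checkpoint genes 16 rose and 2 fell. Lgals9 stood at 266 ± 64.4 against 51.6 ± 16.2 CPM, Cd47, the "do not eat me" signal, at 266 ± 32.3 against 128 ± 43.5 CPM, and Tigit was lower in lung at 2.56 ± 0.466 against 10.2 ± 4.45 CPM. The call of Cd47 was lost without any one of lung replicate 1 or 3 or cell line replicate 2 or 3, with edgeR adjusted p between 0.059 and 0.119. The camera adjusted p with the preset was at most 0.000112 for these lists, the value of the checkpoint genes. With an estimated correlation it was 0.0581 for interferon-stimulated genes, 0.0651 for class I, 0.171 for class II, 0.141 for complement and 0.152 for checkpoint genes.

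Trp53, the p53 tumour suppressor gene, rose in lung, while Myc and the tumour suppressor gene Cdkn2a fell. Trp53 stood at 51.5 ± 7.83 CPM in lung and 7.24 ± 1.58 CPM in the cell line (log2 fold change 2.83, SE 0.28, edgeR adjusted p = 0.000118). Myc stood at 58.0 ± 10.2 against 253 ± 61.6 CPM and Cdkn2a at 82.2 ± 54.6 against 244 ± 6.97 CPM. The call of Cdkn2a was lost without lung replicate 1 (adjusted p = 0.0752) or cell line replicate 1 (adjusted p = 0.0505), and its log2 fold change of -1.57 was -2.29 without lung replicate 2.

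Several growth-related programmes were lower in whole lung than in the cultured line. Of 15 genes of MAPK output 11 fell, with Ccnd1, the cyclin D1 gene, at 338 ± 81.0 against 1374 ± 536 CPM and Epha2 at 79.0 ± 29.3 against 569 ± 124 CPM, and 2 rose, with Spry1 at 79.9 ± 6.24 against 7.12 ± 1.16 CPM. Of 15 glycolysis genes 13 fell, with Pkm at 670.5 ± 60.0 against 3528 ± 852 CPM and Gapdh at 1046 ± 371 against 3494 ± 273 CPM. Of 16 cholesterol synthesis genes 14 fell, with Srebf2 at 204 ± 48.9 against 464 ± 19.8 CPM and Fdps at 137 ± 49.3 against 308 ± 84.6 CPM. That count was 9 when scaled by library size alone or without lung replicate 1, and Fdps missed the threshold without lung replicate 1 or 3 or cell line replicate 1 (edgeR adjusted p 0.0547 to 0.0877). Of 15 ribosome biogenesis genes 14 fell, with Npm1 at 585 ± 195 against 1916 ± 132 CPM and Ncl at 357 ± 68.3 against 1883 ± 289 CPM. The number of MAPK output genes that rose was 1 without any 1 of the samples but lung replicate 2. The camera adjusted p with the preset was at most 0.000965 for these lists, the value of MAPK output. With an estimated correlation it was 0.317 for MAPK output, 0.0522 for glycolysis, 0.106 for cholesterol synthesis and 0.234 for ribosome biogenesis.

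Of 22 proliferation genes 5 fell and 17 did not pass the test, and 1 passed when adjusted over the list alone. Mcm2, a replication licensing factor, stood at 57.6 ± 6.81 against 206 ± 55.6 CPM and Mcm7 at 77.3 ± 9.496 against 215 ± 96.8 CPM. In cell line replicate 1 the median of the list was 8.96-fold below the other cell line samples, and without that replicate 21 of the 22 fell. The number was 2 without any 1 of the other samples, and 22 without cell line replicate 1 and lung replicate 2. The list had camera adjusted p = 0.00391 with the preset and adjusted p = 0.554 with an estimated correlation. Of 16 immediate early and dissociation genes 8 fell and 1 rose. Fos stood at 27.8 ± 8.84 against 368 ± 270 CPM and Egr1 at 63.7 ± 26.3 against 388 ± 274 CPM, with cell line replicate 1 again lower than the others (Fos at 56.8 against 512 and 536 CPM), and Btg2 rose (132 ± 23.6 against 57.8 ± 16.7 CPM). Egr1 missed the threshold without lung replicate 1 (edgeR adjusted p = 0.0516) or lung replicate 2 (0.0634). That list had camera adjusted p = 0.00533 with the preset and adjusted p = 0.335 with an estimated correlation.

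Identity genes were mixed. Of 14 epithelial genes 9 rose and 1 fell. Nkx2-1, the lineage transcription factor of lung epithelium, stood at 104 ± 24.4 CPM in lung and at 0 counts in the cell line, at least 1982-fold higher, and Muc1 at 326 ± 104 against 55.9 ± 14.8 CPM. Krt18, a keratin, was lower in lung (696 ± 287 against 2133 ± 824 CPM). The list had camera adjusted p = 0.00268 with the preset and adjusted p = 0.237 with an estimated correlation. Of 13 mesenchymal genes 5 fell and 3 rose (camera adjusted p = 0.199). Fn1 stood at 849 ± 410 against 2372 ± 200.2 CPM and Vim at 1572 ± 252 against 3367 ± 1247 CPM, while Lox, a collagen cross-linking enzyme, stood at 65.2 ± 25.4 against 0.292 ± 0.117 CPM. The median of the mesenchymal list, -0.19, was 0.06 when scaled by library size alone and 0.02 without cell line replicate 3. The call of Vim was lost without lung replicate 1 or 3 or cell line replicate 2 or 3 (edgeR adjusted p 0.112 to 0.14) and with the replicate number as a block (0.0813), that of Fn1 without cell line replicate 2 or 3 (0.0509 and 0.0572), and that of Krt18 without lung replicate 1 (0.0672) or lung replicate 3 (0.0536).

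Of 16 p53 targets 6 rose and 1 fell, with a median log2 fold change of 0.01 and a mean of 0.65 (camera adjusted p = 0.9998). Cdkn1a, the p21 gene, stood at 69.6 ± 9.73 against 16.7 ± 6.96 CPM, Phlda3 at 39.1 ± 11.5 against 13.2 ± 0.959 CPM, and Aen at 28.3 ± 1.42 against 50.5 ± 4.31 CPM. With 1 sample left out the median lay between -0.34 (without cell line replicate 2 or 3) and 0.40 (without cell line replicate 1, where 7 rose and 2 fell), and without cell line replicate 1 and lung replicate 2 it was 0.54, with 9 higher and 4 lower. Aen missed the threshold without lung replicate 1 or 3 or cell line replicate 2 (edgeR adjusted p 0.0521 to 0.0584). Of 17 matrix proteases and their inhibitors 7 rose and 2 fell (camera adjusted p = 0.244), with Timp3 at 384 ± 170.1 against 9.90 ± 0.754 CPM, Mmp2 at 131 ± 57.8 against 0.354 ± 0.210 CPM, and Mmp13 at 7.82 ± 1.85 against 45.9 ± 47.1 CPM, which missed the threshold without lung replicate 2 (edgeR adjusted p = 0.0593). Mmp13 stood at 100.3 CPM in cell line replicate 1 against 19.0 and 18.3 CPM in the others, and its log2 fold change of -2.55 was -1.26 without that replicate. Of 36 cytokine and growth factor genes tested, 21 rose and 7 fell (camera adjusted p = 0.0654 with the preset, and adjusted p = 0.1595 with an estimated correlation). With the preset it lay between 0.0194 and 0.0431 without 1 lung replicate and between 0.0898 and 0.096 without 1 cell line replicate. Pdgfb stood at 92.1 ± 16.4 against 26.9 ± 3.47 CPM, Tgfb3 at 58.1 ± 17.2 against 16.2 ± 4.39 CPM, and Csf3, the granulocyte growth factor G-CSF, at 0.307 ± 0.225 against 4.75 ± 2.96 CPM. The log2 fold change of Csf3 was -3.94, with -4.68 without lung replicate 2 and -3.33 without cell line replicate 1.

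**Figure D4:**
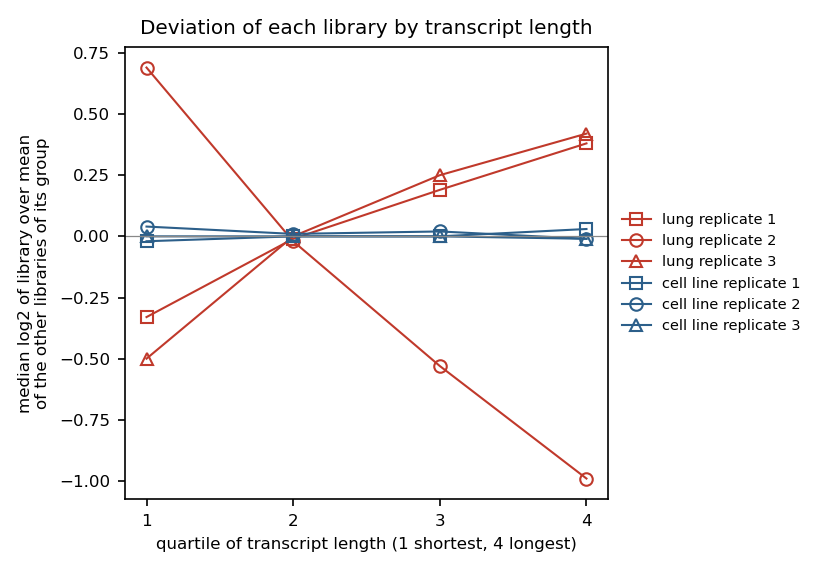
Median log2 ratio of each library to the mean of the other libraries of its group on the y axis, by quartile of transcript length on the x axis, over 10475 genes at a mean of 10 CPM or more. Lines are single libraries (lung red, cell line blue): lung replicate 2 runs from 0.69 in the shortest to -0.99 in the longest quartile, and the cell line libraries stay between -0.02 and 0.04.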

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

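With 3 samples in each group, no sample was tested as an outlier. Of the unmatched transcripts, 2 stood out because they were abundant in lung and had 0 counts in every cell line sample, outside the genes compared. ENSMUST00000192630 averaged 40183 ± 5738 estimated counts in lung (39490, 34823 and 46236 in replicates 1, 2 and 3). ENSMUST00000215695 averaged 2931 ± 2652 estimated counts in lung, with 3628 and 5165 in replicates 1 and 3 and 0 in replicate 2. Neither has a gene name in the annotation used, and both stood outside every comparison of the report.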

How the results depend on the processing

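The alternatives below were chosen before the data were examined, except leaving out cell line replicate 1 together with lung replicate 2, which was chosen after the data had been seen. Requiring 10 counts in all 6 samples, which tests fewer genes by construction, gave 2555 genes, 15 ligands and 8 receptors higher and 1701 genes lower. The other counts of genes, ligands and receptors that rose lay within 1.5 times of the reported ones. Genes that fell numbered 1728 with library size alone, 703 with glmTreat, which asks for a larger change by construction, and 5425 without the 2 libraries, and the cause of the last was not tested. The fit without the 2 libraries kept only the closest pair of samples in each group. The spread within groups in its test came from those pairs, and the cell line pair may be technical. Leaving out each replicate in turn gave 4249 to 5190 genes higher, 1820 to 3773 lower, 27 to 30 ligands and 18 to 20 receptors higher. Ligands that fell numbered 0 with library size alone, 10 counts in all samples, limma-voom and glmTreat, 2 with no filter and with DESeq2, and 0 to 2 with a replicate left out, and the cause was not tested. For Cxcl1 the adjusted p ranged from 0.00372 to 0.167 over its alternatives. Receptors that fell numbered 1 without the 2 libraries and 0 elsewhere. Detected ligands numbered 14 to 17 in the cell line and 35 to 36 in lung.

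Of 114 named genes, 2 changed direction, and neither had passed the test. Cxcl5 ranged from -1.28 to 0.63 with a replicate left out, the latter without cell line replicate 1, where its level was highest, and was 0.44 without the 2 libraries (edgeR adjusted p = 0.00963, with a range of 0.00963 to 0.853 over its alternatives). Cx3cl1 ranged from -0.02 without cell line replicate 1 to 0.49 without lung replicate 2, and was 0.29 without the 2 libraries (edgeR adjusted p = 0.0212, range 0.0212 to 1). For both genes, the edgeR adjusted p without the 2 libraries took its spread from the closest pair of samples in each group. Those pairs were kept after the data had been seen, so nothing is concluded from these p-values. Requiring 10 counts in all 6 samples left 79 of the 114 named genes tested, of which 4 lost their call. Calls lost numbered at most 4 under the scalings and 14 with glmTreat, and 2 to 8 with a replicate left out. Deviations of same-numbered samples correlated at -0.05, 0.09 and -0.10 across genes, within the range of differently numbered ones (-0.12 to 0.12). No pairing by number was seen, but 3 samples per group cannot exclude a shared experiment or handling. The replicate block gave 4634 genes higher and 2526 lower, and 112 of 114 named genes kept direction and side of the threshold. The simulated test recovered 4% of 2-fold changes, but it changed only 100 of 15010 genes at each fold size. In these data 48.8% of tested genes passed, so the adjusted threshold was stricter in the simulation. Its recovery is therefore not that of the comparison of lung with the cell line. A gene below the threshold is still not shown to be equal.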

Other observations

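All tests weighed in this part, the splits of the samples included, were written down after the results they measure had been seen. Growth factors that fell in lung included 3 ligands of the epidermal growth factor receptor, named here after their values were seen. Areg stood at 10.4 ± 2.60 CPM in lung and 122 ± 59.2 CPM in the cell line, Ereg at 5.39 ± 2.12 against 74.5 ± 44.9 CPM, and Hbegf at 48.2 ± 2.63 against 186 ± 105 CPM (edgeR adjusted p = 0.00047, 0.00133 and 0.0107). The colony-stimulating factor Csf2, at 2.34 ± 0.822 against 15.3 ± 9.16 CPM, the cytokine Lif, at 15.9 ± 4.83 against 87.1 ± 49.2 CPM, and Spp1, which encodes osteopontin, at 1173 ± 165 against 2651 ± 526 CPM, fell as well (edgeR adjusted p = 0.00581, 0.00538 and 0.0147).

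Genes well expressed in the cultured line were seldom near absent from lung. Other lung cells may express the same genes, so this does not measure how much KP transcript the lung samples held. Of 7008 genes at 20 CPM or more in every cell line sample, 45 stood below 10% and 16 below 5% of their cell line level in lung, and the median was 71.0%. Among the genes with the largest falls, Add2 stood at 0.735%, Bcat1 at 0.840%, Dynap at 0.94% and Grem1 at 2.02%. Hmga2, a chromatin protein of fetal tissue, stood at 2.71%. Hmga2 was named after its values were seen.

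The cell line samples held lymphoid and red cell transcripts, such as Ighm at 167 ± 50.8 CPM, Igkc at 92.4 ± 25.3 CPM, Hbb-bs at 6.44 ± 1.93 CPM, and the spleen genes Slc40a1 at 23.3 ± 7.99 and Cr2 at 12 ± 3.05 CPM. Carry-over from the lung libraries would bring lung epithelial transcripts along, and these stood at 0.00166% of their lung level against 32.8% for B and plasma cell markers, which argues against it. Transcription by the KP cells would leave replicates 2 and 3 alike, but the median log2 ratio of replicate 3 to replicate 2 was -0.78 for B and plasma cell markers (SE 0.04), -0.84 for T cell markers (SE 0.22) and -0.51 for monocyte and macrophage markers (SE 0.12), against 0.00 for all genes. Each SE in this paragraph is over the genes of a list within 1 pair of libraries. Genes are not independent replicates, so such an SE does not measure the spread between preparations. A candidate explanation is 1 admixed source of spleen-like RNA, as admixed cells, RNA or library could give: the medians of 5 lists, with red cell and erythroid (-0.61, SE 0.61) and spleen genes (-0.63, SE 0.52) included, spanned 0.33, but those of replicate 1 to replicate 2 spanned 0.49 with both signs (T cell -0.23, SE 0.17, and macrophage 0.22, SE 0.07), so more than 1 source stays open as well. Of 13 spleen genes 11 were at 1 CPM or more in all lung samples and 9 in all cell line samples, and 0 belong to another list. No sort is named in the labels. The ligands detected in the cell line samples did not move as 1 set from replicate 2 to 3. The ratio was 0.989 for Cxcl5 (0.907 to 1.08) and 0.991 for Cx3cl1 (0.897 to 1.095), but 0.557 for Cxcl12 (0.458 to 0.673). These intervals cover counting error alone, and they argue against the same source for all of the detected ligands. Which of the 15 ligands and 4 receptors came from the KP cells stays open.

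Cell line replicate 1 had high stress genes and low proliferation genes. Of 20 genes of the unfolded protein and integrated stress response, 19 were at least 2-fold above the mean of the other cell line samples (median 6.11-fold), with Ddit3 at 249.8 against 4.32 and 5.06 CPM, and 21 of 22 proliferation genes were at least 2-fold below it. Fewer counts do not account for it, as replicate 1 had 22.69 M estimated counts, the most of the 3, nor does admixed lung, as lung epithelial genes stood at 0.000469% of their lung level there. More of the spleen-like RNA is argued against too, since the median of the stress genes stood 2.14 further above the other samples on the log2 scale than that of the B cell genes. What stays open is the state of the culture or a different handling, and no biological explanation was tested.

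Lung replicate 2 differed from the other lung samples by transcript length. The median deviation fell by 1.69 on the log2 scale from the shortest quartile of transcripts (median length 1322 bases) to the longest (6044 bases), over 10475 genes, as fragmented RNA could give. More blood in that sample alone is argued against, since 23.3% of genes outside the red cell list lay 2-fold or more away from the other lung samples. In the lung samples 1 and 3 the median log2 ratio to the cell line was -0.29 in the shortest and -0.26 in the longest quartile, and in lung replicate 2 it was 0.51 and -1.16. The fitted log2 fold change over all samples had a median of 0.03 in the shortest and -0.51 in the longest quartile. The reported fold changes therefore include a trend with length. Without lung replicate 2, 5148 genes were higher and 3773 lower in lung. Other differences in library preparation that act by length stay open.

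There are 10 ways to split the 6 samples into groups of 3, too few for a share under 0.05. The split into lung and cell line gave 7422 genes, 30 ligands and 19 receptors past the threshold, and the highest of the other splits gave 0 of each, with 1 of the 10 splits giving as many. Every other split put lung and cell line samples in both groups, so their difference entered the spread within groups. Few calls in those splits were fixed by the design, and nothing is concluded from them.

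Of the other marker lists added after the data were seen, medians in the cell line stood at 34.1% of the lung level for spleen genes, 24.8% for erythroid precursors, 8.84% for thymocyte, 8.45% for bone marrow granulocyte precursor, 0.756% for liver, 0.445% for lung endothelium and 0.806% for fibroblast genes. Few genes of the erythroid, thymocyte and granulocyte lists were at 1 CPM or more in all lung samples (2, 2 and 1). The 7 NRF2 targets at 1 CPM or more stood 1.88-fold higher in cell line replicate 1 at the median.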
